A study of Mus musculus with 6 samples.

How the data were processed

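RNA was measured on 6 expression arrays, 3 from p300-deleted and 3 from control mouse regulatory T cells. Groups were taken from the genotype in the labels, fl-p300/Foxp3cre against Foxp3cre, and samples are named by group and by the replicate number in their titles. The labels call the samples independent but do not say whether each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

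The deposited table holds log2 values per probe set, made with RMA per the submitters' processing notes. RMA corrects background, brings the arrays to a common distribution by quantile normalization and summarises the probes of each probe set. Its version is not given in the sources used here. Because quantile normalization gives every array nearly the same distribution, a change in total RNA per cell would not be visible, and differences of dim probe sets are compressed by background. Array medians lay between 5.38 and 5.46. The bacterial control probe sets, which match no mouse transcript, had medians per array of 2.12 to 2.26, and the hybridization spike-ins rose in the order bioB, bioC, bioD and cre with means of 8.55, 10.08, 12.02 and 13.68. The number of arrays, 3 per group, limits the precision.

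The table has 22690 probe sets, of which 64 are controls. The platform annotation gave 1 gene symbol for 20393 probe sets, several for 691 and none for 1606. Of the probe sets with 1 symbol, 20364 were matched by gene ID to the RefSeq gene table of assembly GRCm38.p6, with 0 symbols updated, and 29 kept the annotation's symbol. No coordinates are given, since no genome build applies to the deposited values. For each of 12393 genes the probe set with the highest mean over all 6 arrays was used, and 4957 genes had more than 1. The 30% of genes with the lowest means (below 3.91 on the log2 scale, 3718 genes) were left out, which left 8675 genes to test.

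Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with no covariate and Benjamini-Hochberg adjustment over the 8675 genes, and a gene was called changed at an adjusted p under 0.05. Fold changes are p300-deleted minus control on the log2 scale, with the standard error (SE) of the moderated fit. The median SE was 0.126. The 30 gene lists were fixed before the data were examined and compared with camera of limma at its preset correlation of 0.01, adjusted over the 30 lists. The same lists were run with a correlation estimated from the residuals and with fry, whose directional p asks whether the genes of a list move on balance in one direction. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone.

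Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose 3 arrays of one group all lay on one side of the 3 of the other. From each list it added up to 4 members past the threshold, or up to 2 as values where none passed, and it always took Foxp3 and the p300 paralogue Crebbp. Any other named gene was chosen after its values were seen. Of the genes named by the rule, 21 had several probe sets, and for Hsp90aa1, Rad51b, Rps6 and Sc5d a further probe set had the opposite sign. Genes chosen after their values were seen are not in this count. Immunoglobulin genes, the mast cell proteases and the Klrb1 family are multigene families, and probe sets whose identifiers end in _s_at, _x_at or _a_at can bind several transcripts, so values of single members are uncertain. Probe sets with several or no symbols were fitted apart and name no gene.

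The fit was tested on simulated data made from the 8675 genes, with 20 simulated sets of 200 changed genes each. It recovered 31.2% of genes changed by 0.5 on the log2 scale, 81.7% of those changed by 1 and 98.4% of those changed by 2, and 4.29% of its calls were unchanged genes. In the set test 100% of simulated lists shifted by 0.3 and 0% of unchanged lists had an unadjusted p under 0.05. Noise was drawn independently for each gene, so the simulated lists had no correlation between members. Real lists had, with an estimated correlation of 0.80 for cell cycle and 0.60 for myeloid markers. The simulation therefore cannot tell how often such lists are called wrongly.

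Alternatives planned before the data were examined were the filter on dim genes, a further quantile normalization, median centring, the mean of all probe sets of a gene, a trended and robust variance, array weights, the replicate number as a block, leaving out each array, other thresholds, single probe sets and the other set tests. A fit with the mean of the 18S ribosomal RNA control probe sets as a covariate was added after the data had been seen. The planned comparison of Ep300 probe sets was not run, because the annotation names 0 probe sets for Ep300.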

Results

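Gene expression was measured in regulatory T cells (Treg) from mice in which the histone acetyltransferase p300, encoded by Ep300, was deleted with a Cre recombinase driven from Foxp3. By the genotype in the labels, controls carried Foxp3cre without the floxed p300 allele, but their sample titles call them WT. The sources used here do not explain this difference. CD4+CD25+ cells of C57Bl/6 mice were separated magnetically, and 3 p300-deleted samples were compared with 3 controls, 1 array each. By the title of the study, the comparison concerns the role of p300 in Foxp3+ Treg. Array medians on the log2 scale were 5.46, 5.40 and 5.44 in the p300-deleted group and 5.41, 5.38 and 5.44 in the controls. Correlations of the arrays across probe sets were 0.99453 to 0.99591 within the p300-deleted group, 0.98807 to 0.99315 within the controls and 0.98546 to 0.99265 between groups. The mean of the 18S ribosomal RNA control probe sets was 7.74, 9.47 and 7.91 in the p300-deleted arrays and 5.68, 6.03 and 8.69 in the controls. The 3' minus 5' difference of the Gapdh control probe sets, a sign of RNA quality, was 0.09, 0.14 and 0.06 in the p300-deleted arrays and 0.23, 0.59 and 0.21 in the controls, with no overlap between groups, and that of actin was 0.36, 0.43 and 0.29 against 0.40, 0.46 and 0.30.

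The targeted gene could not be used as a check of the labels, because the annotation names 0 probe sets for Ep300, so Ep300 is not analysed here. Its paralogue Crebbp, which encodes the acetyltransferase CBP, had a mean of 7.47 ± 0.08 (SD, n = 3) in p300-deleted cells and 7.43 ± 0.17 (SD, n = 3) in controls. The difference was 0.04 (SE 0.12, adjusted p = 0.892), within the spread between replicates.

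By the brightest probe set of each gene, Foxp3, the lineage transcription factor of Treg, had the largest fall among the genes that passed the test, and Slpi, a secreted inhibitor of serine proteases, the largest rise. Further probe sets of single immunoglobulin genes (up to 2.97), a probe set listing several immunoglobulin heavy chain genes (3.32, SE 0.27, adjusted p = 0.00220) and probe sets with no listed gene (up to 3.97) had larger differences than Slpi (2.79). Of 8675 genes tested, 149 changed, with 86 higher and 63 lower in p300-deleted cells. Of these, 32 were higher and 14 lower by at least 2-fold. At an unadjusted p under 0.05 there were 1570 genes, against 434 by chance. The arrays of the groups did not overlap for any of the 149 genes, nor for 2056 of all tested genes (23.7%, where chance gives 10%). The number of changed genes depended on single arrays. It was 35, 22 and 30 without p300-deleted 1, 2 and 3, and 9, 118 and 230 without control 1, 2 and 3, and with the 18S value as a covariate, a fit added after the data had been seen, it was 15.

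Foxp3, read by the 1 probe set named for the gene, fell by 6.53 on the log2 scale (SE 0.16, adjusted p = 4.36e-07), from 9.46 ± 0.16 (SD, n = 3) in controls to 2.92 ± 0.31 (SD, n = 3) in p300-deleted cells. The p300-deleted arrays read 2.57, 3.04 and 3.15, each below the lower quartile of its own array (3.26, 3.29 and 3.28), and the bacterial control probe sets of those arrays had medians of 2.12, 2.26 and 2.20. The position of this probe set in the transcript and the structure of the Foxp3 allele in each group are not given in the sources used here. Foxp3 was past the threshold under all 15 alternatives run for it, with values from -6.65 to -6.36 and adjusted p from 5.12e-08 to 5.41e-05.

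Of 26 tested signature genes, 3 rose, 3 fell and 20 did not pass, and adjusted over the list alone 3 rose and 4 fell. Penk, the enkephalin precursor, rose by 1.29 (SE 0.15, adjusted p = 0.0144), and Rgs1, a regulator of G-protein signalling, rose by 0.60 (SE 0.11, adjusted p = 0.0458; past the threshold under 7 of 15 alternatives). The calcium-binding proteins S100a6 and S100a4 also fell, S100a6 at -0.91 (SE 0.18, adjusted p = 0.0458) and S100a4 at -0.80 (SE 0.16, adjusted p = 0.0493), and passed under 7 and 5 of 15 alternatives. Several signature genes were looked at after their values were seen. Among them Izumo1r, the folate receptor 4 of Treg, rose by 0.62 (SE 0.12, adjusted p = 0.0458; 7 of 15 alternatives). Differences for Il2ra, which encodes the CD25 used for the separation, Ctla4, Gpr83, Tnfrsf18 and Nrp1 were 0.25, 0.30, 0.32, -0.16 and 0.05, with adjusted p of 0.378, 0.287, 0.246, 0.588 and 0.870. Icos was at -0.69 (adjusted p = 0.205) and Klrg1 at -1.16 (adjusted p = 0.0913). The list was not called by camera (adjusted p = 0.767), and its median of 0.10, its mean of -0.25 and its upward camera direction differ in sign.

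**Figure D1:**
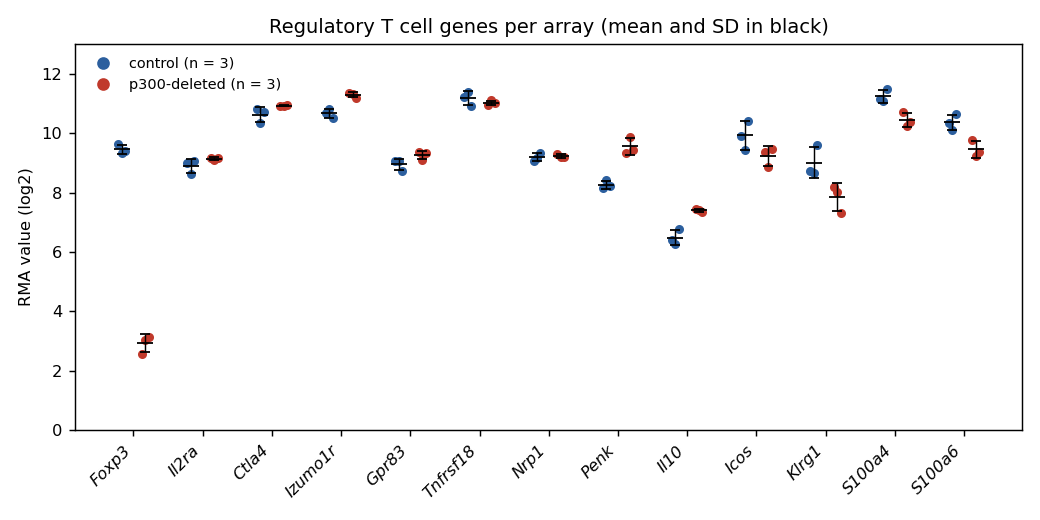
Log2 values of Treg genes on each of the 6 arrays, with p300-deleted and control arrays as separate points and the group means and SD (n = 3) marked. Foxp3 lies at 2.57 to 3.15 in p300-deleted arrays and at 9.35 to 9.63 in controls, while the groups differ by 0.25 for Il2ra and 0.30 for Ctla4.

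Of 15 tested suppressive effector genes of Treg, 1 rose and 14 did not pass (adjusted over the list alone, 2 rose and 1 fell). The gene that rose was Il10, by 0.91 (SE 0.14, adjusted p = 0.0283). Of 21 T helper effector genes 1 rose, both over all genes and adjusted over the list alone. This was Il21, a cytokine of helper T cells, by 1.04 (SE 0.18, adjusted p = 0.0393). Among 17 IL-2 and STAT5 targets 1 rose (adjusted over the list alone, 1), the cytokine Lta by 0.57 (SE 0.11, adjusted p = 0.0467), which passed under 5 of 15 alternatives. The 3 lists were not called by camera, with adjusted p of 0.728, 0.758 and 0.531 and medians of 0.03, -0.05 and 0.05.

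Most of the 12 largest rises were genes of antibody-secreting cells, mast cells and basophils. A kappa variable gene rose by 2.37 (SE 0.17, adjusted p = 0.00109), Igha by 2.14 (SE 0.19, adjusted p = 0.00336), Igkv15-103 by 2.13, Igk by 2.12 and Iglv1 by 1.49. Of 18 tested immunoglobulin genes, a group formed after the values were seen, 9 rose and 17 had positive values. Tnfrsf17, the plasma cell receptor BCMA, rose by 1.80 (SE 0.18, adjusted p = 0.00587). Of 7 tested plasma cell markers 5 rose (7 adjusted over the list alone), including the endoplasmic reticulum proteins Derl3 (1.37) and Txndc5 (1.29). The list had a median of 1.29 and camera adjusted p = 2.08e-09, with adjusted p = 0.347 with an estimated correlation and 0.0369 by fry. Per array, the mean of the list relative to all arrays was 0.86, 0.38 and 0.49 in p300-deleted cells and -0.66, -0.41 and -0.66 in controls. With the mean of all probe sets of each gene the list's median was 0.85, Igk was at 1.31, and Iglv1 at 0.83 and Txndc5 at 0.85 no longer passed. Neighbouring immunoglobulin genes are similar in sequence, so the values of single V genes are uncertain.

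Of 13 tested B cell markers 1 fell and 12 did not pass (adjusted over the list alone, 1 rose and 2 fell), with a median of -0.22 and camera adjusted p = 0.531. The member that fell was Spib, a transcription factor of B cells and plasmacytoid dendritic cells, by 0.95 (SE 0.16, adjusted p = 0.0368). Without p300-deleted 1 the list was called as lower, with a median of -0.27 and adjusted p = 0.0269, against adjusted p of up to 0.952 under the other alternatives. Its median turned positive, at 0.05 (camera adjusted p = 0.912), without p300-deleted 2 and was -0.01 with the 18S covariate.

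Mcpt8, a basophil protease, rose by 2.53 (SE 0.43, adjusted p = 0.0374), Fcer1a, a chain of the high-affinity IgE receptor, by 1.67 (SE 0.25, adjusted p = 0.0244) and the mast cell protease Cma1 by 1.67 (SE 0.24, adjusted p = 0.0223). Mcpt4 (1.38), Tpsb2 (1.10) and Cpa3 (1.04, past the threshold under 6 of 15 alternatives), chosen after their values were seen, also rose. Of 16 other mast cell and basophil markers, chosen after these rises but before their own values were seen, 6 were tested. All 6 had positive values, with a median of 0.20, but 0 rose in limma (1 at an unadjusted p under 0.05, 0 adjusted over the list alone). Among them Tpsab1 and Slc45a3, with means of 3.92 and 3.945 over all arrays, lay close to the dim limit of 3.91. Slpi rose by 2.79 (SE 0.32, adjusted p = 0.0104), Klrb1b, a lectin-like receptor of NK cells, by 2.30 (SE 0.41, adjusted p = 0.0405; past the threshold under 6 of 13 alternatives) and Sh3gl3, an endophilin of membrane traffic, by 1.57 (SE 0.14, adjusted p = 0.00336).

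All 22 tested myeloid markers had positive values, but 0 passed in limma over all genes (11 at an unadjusted p under 0.05, 6 adjusted over the list alone). Their median was 0.68 (camera adjusted p = 5.05e-07), with adjusted p = 0.599 with an estimated correlation. The neutrophil genes S100a8 and S100a9 were at 2.59 (SE 0.68, adjusted p = 0.101) and 2.43 (SE 0.69, adjusted p = 0.120). The list's mean was 1.29 in p300-deleted 1 against 0.08 and 0.11 in the other p300-deleted arrays, and -0.56, -0.86 and -0.06 in controls, and without p300-deleted 1 the median was 0.39. Of 12 NK and cytotoxic markers 1 rose (7 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 0.00363) and adjusted p = 0.522 with an estimated correlation. The gene past the threshold was the protease Gzma, which rose by 0.73 (SE 0.14, adjusted p = 0.0445). This list's call was lost when the dimmest 50% of genes were left out (median 0.18, adjusted p = 0.339) and with array weights (adjusted p = 0.0856), and over all alternatives its adjusted p ran from 9.56e-05 to 0.522.

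**Figure D2:**
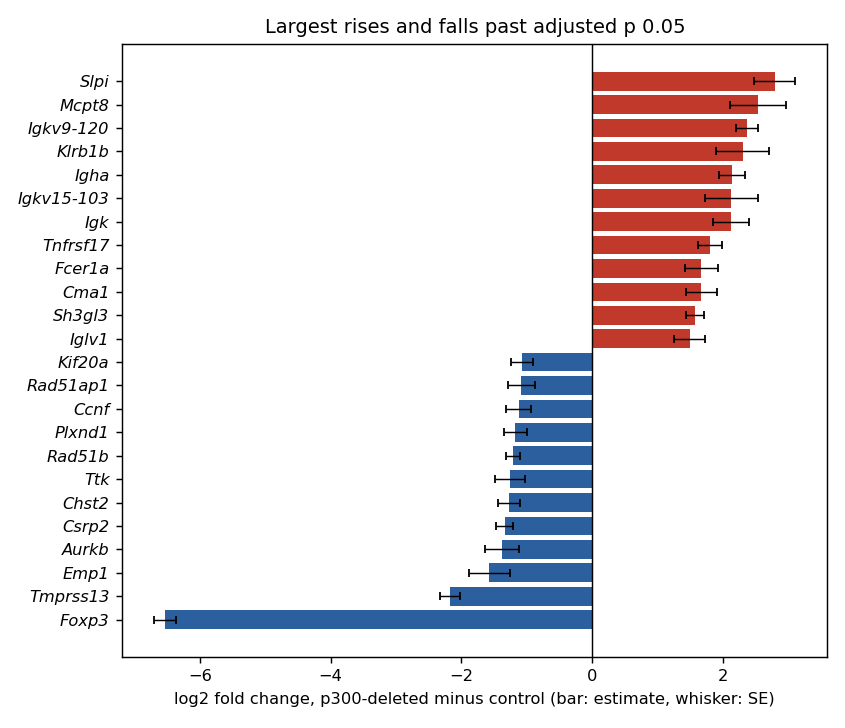
Log2 fold change of the 12 largest rises and the 12 largest falls, p300-deleted minus control, as bars with whiskers for the SE of the limma fit (n = 3 arrays per group). Rises run from 1.49 (Iglv1) to 2.79 (Slpi), and Foxp3 at -6.53 lies apart from the next fall, Tmprss13 at -2.18.

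Of 34 tested cell cycle genes, 7 fell and 27 did not pass over all genes, and 27 fell adjusted over the list alone. The median was -0.87 (camera adjusted p = 1.46e-17), with adjusted p = 0.522 with an estimated correlation and 0.164 by fry. The mitotic kinases Aurkb and Ttk fell, Aurkb at -1.38 (SE 0.26, adjusted p = 0.0445) and Ttk at -1.26 (SE 0.23, adjusted p = 0.0440). The mitotic kinesin Kif20a fell by 1.07 (SE 0.16, adjusted p = 0.0258) and Ccne1, the G1/S cyclin E1, fell by 0.88 (SE 0.13, adjusted p = 0.0223). Further members were looked at after their values were seen, the proliferation marker Mki67 at -1.08 (SE 0.34, adjusted p = 0.156) and Pcna, the sliding clamp of DNA replication, at 0.18 (SE 0.17, adjusted p = 0.640). List means were -0.15, -0.57 and -0.50 in p300-deleted arrays and 0.28, 0.05 and 0.90 in controls. These arrays do not overlap, and the median without control 3 was -0.60.

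Among the other large falls, Rad51b and Rad51ap1, which act in homologous recombination, fell, Rad51b at -1.21 (SE 0.11, adjusted p = 0.00336) and Rad51ap1 at -1.08 (SE 0.20, adjusted p = 0.0450), and a second, dim probe set of Rad51b was at 0.17. Further probe sets of Rad51ap1 were at -1.08, -0.31 and -0.02, its value with the mean of all its probe sets was -0.62, and it passed under 6 of 14 alternatives. Ccnf, cyclin F, fell by 1.13 (SE 0.19, adjusted p = 0.0392). Tmprss13, a membrane serine protease, fell by 2.18 (SE 0.16, adjusted p = 0.00109). Emp1, an epithelial membrane protein, fell by 1.58 (SE 0.31, adjusted p = 0.0493) but passed under only 4 of 14 alternatives. Csrp2, a LIM-domain protein, fell by 1.34 (SE 0.13, adjusted p = 0.00554). Chst2, a sulfotransferase, fell by 1.28 (SE 0.17, adjusted p = 0.0203) and Plxnd1, a semaphorin receptor, fell by 1.18 (SE 0.18, adjusted p = 0.0244).

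Of 22 genes of the unfolded protein response 1 rose (4 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.03e-06) and adjusted p = 0.522 with an estimated correlation. The gene was Xbp1, a transcription factor of this response and of plasma cells, which rose by 0.73 (SE 0.14, adjusted p = 0.0479) and passed under 6 of 15 alternatives. The list's means per array were 0.32, 0.06 and 0.10 in p300-deleted cells and -0.17, -0.23 and -0.08 in controls, with the highest value in p300-deleted 1, as for the plasma cell (0.86) and myeloid (1.29) markers. Of 28 interferon response genes 0 passed in limma (5 at an unadjusted p under 0.05, 0 adjusted over the list alone), with Oasl2 at 1.15 (adjusted p = 0.0764) and Ifit3 at 0.87 (adjusted p = 0.0936). The interferon list had a median of 0.22 (camera adjusted p = 0.00014), adjusted p = 0.777 with an estimated correlation, arrays that overlap between the groups, and a median of 0.11 without control 3. Of 26 immediate early genes 2 rose (3 adjusted over the list alone), Jun by 0.95 (SE 0.16, adjusted p = 0.0390) and Rgs1, with a list median of 0.19 (camera adjusted p = 0.00765) and adjusted p = 0.522 with an estimated correlation. The immediate early call was lost without control 2 (median 0.06, adjusted p = 0.205) and with array weights (median 0.12, adjusted p = 0.0856), its median was 0.09 without p300-deleted 1, and its adjusted p over the alternatives ran from 0.00105 to 0.522.

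Of 21 hypoxia and glycolysis genes 0 passed in limma (5 lower at an unadjusted p under 0.05, 3 fell adjusted over the list alone). Tpi1, triose phosphate isomerase, was at -0.50 (SE 0.10, adjusted p = 0.0517) and Mif at -0.42 (SE 0.13, adjusted p = 0.153). The list's median was -0.22 (camera adjusted p = 0.00464), with adjusted p = 0.347 with an estimated correlation and 0.00877 by fry. Of 17 cholesterol synthesis genes 0 passed in limma (1 higher and 7 lower at an unadjusted p under 0.05, 1 rose and 6 fell adjusted over the list alone), with Idi1 at -0.49 (adjusted p = 0.110) and Sc5d at 0.46 (adjusted p = 0.175). Its median was -0.23 (camera adjusted p = 0.00957), with adjusted p = 0.522 with an estimated correlation. This call was lost when the dimmest 50% of genes were left out (adjusted p = 0.0527, range over the alternatives 0.00434 to 0.522).

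**Figure D3:**
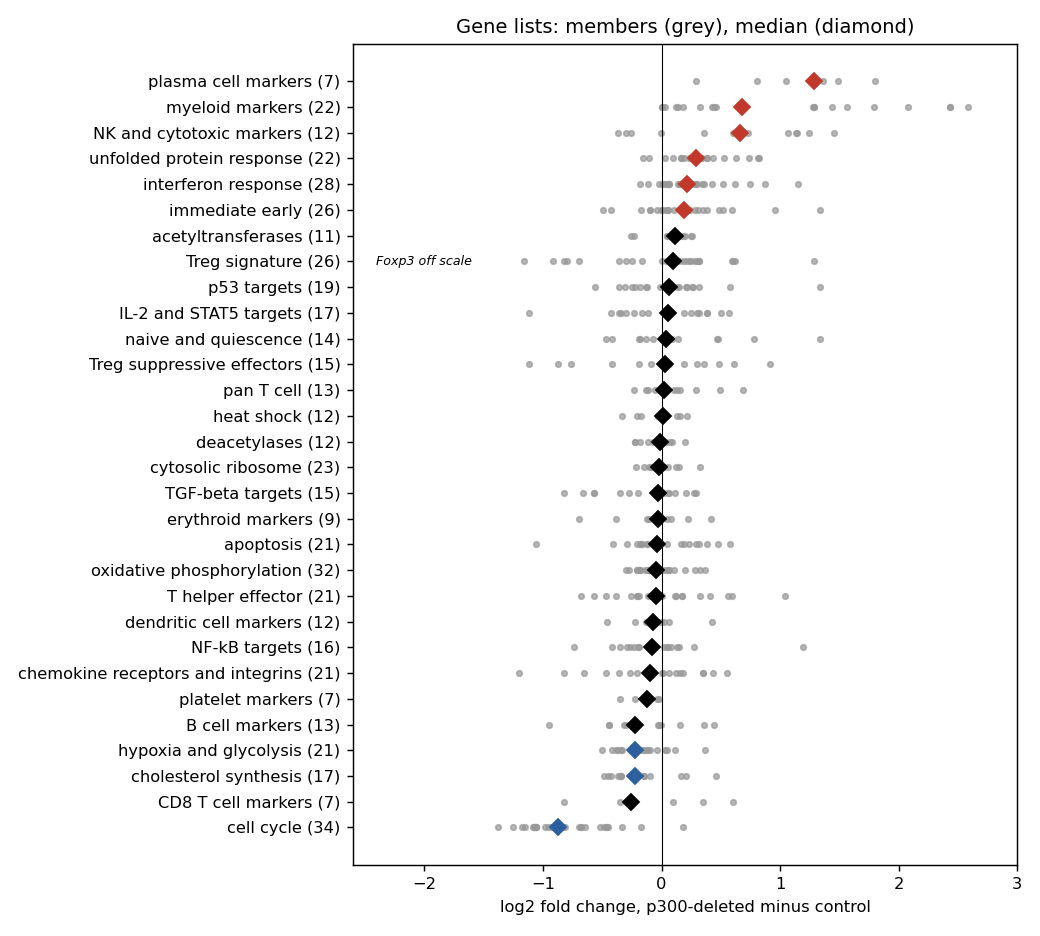
Median log2 fold change of each of the 30 gene lists (diamonds) with the values of their tested members as points, p300-deleted minus control, with red and blue diamonds for lists higher and lower at a camera adjusted p under 0.05, black diamonds for the others, and Foxp3 off the scale. Of the 30 lists 9 are coloured, 6 higher and 3 lower, from -0.87 for cell cycle to 1.29 for plasma cell markers.

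In all, 9 of 30 lists were called, and for 8 of the 9 the list means of the arrays did not overlap between groups. List means also did not overlap for the uncalled Treg signature, acetyltransferase, TGF-beta target and platelet marker lists. With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05, camera of limma), and by fry 2 did. The 21 lists without a call included lists with single changed genes. Among 21 apoptosis and 19 p53 target genes 1 rose in each (1 rose and 1 fell, and 2 rose and 1 fell, adjusted over the list alone), the death receptor Fas by 0.58 (SE 0.11, adjusted p = 0.0458), which passed under 6 of 15 alternatives. The lists had medians of -0.03 and 0.07 and camera adjusted p of 0.693 and 0.531. Pan T cell genes had a median of 0.02 (camera adjusted p = 0.245), with Cd4, a marker of the separation, at 0.68 (adjusted p = 0.0746) and Cd2 at 0.49 (adjusted p = 0.0511). Naive and quiescence genes had a median of 0.04 (camera adjusted p = 0.693), with Btg2 at 1.34 (adjusted p = 0.0810) and Lef1 at 0.78 (adjusted p = 0.156).

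Acetyltransferases had a median of 0.11 (camera adjusted p = 0.301), with Ncoa1 at 0.26 and Hat1 at -0.25, and deacetylases a median of -0.01 (camera adjusted p = 0.824), with Hdac6 at -0.23 and Hdac5 at -0.22. NF-kB targets had a median of -0.08 (camera adjusted p = 0.728), with Tnfaip3 at 1.19 and Ccl22 at -0.74. TGF-beta targets had a median of -0.03 (camera adjusted p = 0.607), with Itgae at -0.82 and Cdkn2b at -0.67. Chemokine receptors and integrins had a median of -0.10 (camera adjusted p = 0.767), with Ccr2 at -1.20. Oxidative phosphorylation genes had a median of -0.04 (camera adjusted p = 0.767), with Cox7c at 0.36 and Ndufs1 at 0.32. Cytosolic ribosome genes had a median of -0.02 (camera adjusted p = 0.972), with Rps6 at 0.33 and Rpl14 at -0.21, and heat shock genes a median of 0.01 (camera adjusted p = 0.972), with Bag3 at 0.22 and Hsp90aa1 at -0.33. Dendritic cell markers had a median of -0.07 (camera adjusted p = 0.972), with Batf3 at -0.46 and Itgax at 0.43, and CD8 T cell markers a median of -0.26 (camera adjusted p = 0.972), with Gzmk at 0.60. Erythroid markers had a median of -0.03 (camera adjusted p = 0.767), with Alas2 at -0.69 and Hba-a2 at 0.42, and platelet markers a median of -0.12 (camera adjusted p = 0.531), with Pf4 at -0.35 and Itgb3 at -0.22. None of the genes named in this paragraph passed the threshold in limma over all genes, with adjusted p of 0.0681 (Gzmk) to 0.664 (Rpl14). Median, mean or camera direction differed in sign for the suppressive effector, T helper, IL-2 and STAT5, apoptosis, cytosolic ribosome and heat shock lists.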

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

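The tests of a replacement of Treg, of plasma cell against B cell markers and of a dilution of T cells, and the fit with an 18S covariate, were chosen after the results they bear on had been seen. The held-out markers were chosen after the rises in plasma cell, mast cell and basophil, and myeloid genes had been seen, but before their own values were.

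Without the control probe sets, 2246 probe sets list no gene or several genes, and no gene comparison uses them. Of these, 19 were higher and 2 lower in p300-deleted cells than in controls (limma over 22626 probe sets, adjusted p under 0.05). Of the 19, 14 list no gene and 5 list several. The largest rises among those without a listed gene were 3.97 (SE 0.28, adjusted p = 0.00104) and 3.09 (SE 0.21, adjusted p = 0.00104), and a probe set listing several immunoglobulin heavy chain genes was at 3.32 (SE 0.27, adjusted p = 0.00220). The 2 lower probe sets list no gene and were at -3.01 (SE 0.41, adjusted p = 0.0314) and -0.93 (SE 0.15, adjusted p = 0.0422).

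The Foxp3 probe set read near background in p300-deleted cells. A replacement of Treg by cells without the signature would take the rest of the signature down too. The median of the other 25 tested Treg signature genes was 0.151, which argues against such cells. It cannot exclude a replacement by CD4+CD25+ cells that express these genes as well, since the median would then stay in place. A difference between the Foxp3 alleles of the groups in the part of the transcript that the probe set reads may give the same picture. It cannot be told apart from a loss of the transcript, because the annotation names 1 probe set for Foxp3 and no other part can be read. A lower Foxp3 transcript level with p300 deleted stays open and was not tested.

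The plasma cell and myeloid lists were called as higher in p300-deleted cells by camera, calls lost with an estimated correlation (adjusted p = 0.347 and 0.599; 5 of 7 and 0 of 22 genes passed in limma), and mast cell and basophil genes had no fixed list. A lower share of Treg, if it raised all other cell types alike, would raise plasma cell and B cell markers equally. The plasma cell median lay 1.51 above the B cell median. Plasma cell list means per array did not overlap between groups and B cell means did, so these lists did not rise alike. Both results were known when the comparison was chosen, so it describes them and is no independent test of an equal rise. The permutation over 7 and 13 genes (p = 0.00101) takes genes as independent and does not measure the spread between samples. A lower share that raised cell types unequally was not tested. RNA of other cells in the preparation may contribute and cannot be told apart from expression in the Treg themselves, since the held-out markers did not decide it. Of 40 held-out markers of mast cells, basophils, neutrophils and macrophages, 18 were tested. Their median was 0.463, short of the 0.5 set for this explanation but at the 100th percentile of 10000 random lists of matched expression. The random lists take genes as independent, so the percentile does not measure the spread between samples. Medians were 0.20 for 6 mast cell and basophil, 1.02 for 5 neutrophil and 0.69 for 7 macrophage markers, and no plasma cell marker was held out. Of the 18, 16 were positive and 5 rose adjusted over these 18 alone (0 over all genes in limma, 7 at an unadjusted p under 0.05), with Slc40a1 at 2.08 and Chil3 at 1.86, while the brightest, Apoe, Axl and Mmp9, were at -0.59, 0.65 and -0.25; selection on CD4 and CD25 would be meant to remove these cells. A different share of antibody-secreting or basophil cells in p300-deleted mice stays open and was not tested.

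The cell cycle list was called as lower in p300-deleted cells by camera, with 7 of 34 genes past the threshold in limma, a call lost with an estimated correlation (adjusted p = 0.522) and by fry (0.164). Dilution of the T cells by cells without T cell genes would lower T cell genes too. The median of the pan T cell genes was 0.0235, which argues against such dilution. This median cannot exclude dilution of cycling T cells by other T cells, since it would then stay in place. With the 18S value, which differed between arrays, as a covariate the cell cycle median was -1.18, and 15 genes in all passed. This fit cannot decide on carry-over of ribosomal RNA, because it assumes a common slope in both groups. Among controls the highest 18S value (8.69, control 3) went with the highest list mean (0.90). Among p300-deleted arrays the highest (9.47, p300-deleted 2) went with the lowest list mean (-0.57). Less proliferation of Treg without p300, or a different share of cycling cells among those separated, may account for it and was not tested.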

How the results depend on the processing

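The 18S covariate was chosen after the data had been seen. Against 149 changed genes, 95 passed with the mean of all probe sets, 1019 with array weights, 15 with the 18S covariate, 46 with a fold of at least 2 required and 399 at an adjusted p under 0.1. Leaving out 1 array gave 9 (without control 1) to 230 (without control 3). With the replicate number as a block 98 passed, and the block ended no list call. The labels do not say that the numbers pair the samples. Correlations of same-numbered deviations were -0.0741, 0.123 and -0.12, too few to settle it. The counts under the other alternatives lay within 1.5 times. Tested one by one, 103 of 22626 probe sets passed. Median centring gave 67 higher and 70 lower. Against 9 called lists, 0 passed with an estimated correlation (2 at an unadjusted p under 0.05, camera) and 2 by fry. Leaving out 1 array gave 8 (control 2) to 10 (p300-deleted 1, with the B cell list added). Of 57 named genes past the threshold, 0 changed sign under the alternatives fitted per gene in limma, although a further probe set of Rad51b (0.17) has the opposite sign. The groups did not overlap for these genes, so leaving out an array could not reverse a sign. Of the 57, 7 passed in every alternative that held them, among them Foxp3, Igha, Sh3gl3, Tmprss13, Csrp2 and Rad51b. Of 15 alternatives, 14, 14 and 13 held Tmprss13, Csrp2 and Rad51b. Their means in p300-deleted arrays, 3.15, 3.91 and 3.79, lay near or below the dim limit of 3.91. The cause of the shifts in the counts of genes and lists was not tested, except that leaving out an array lowers the number of samples and a required fold removes genes. The 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real split gave 149 genes and the highest other 1 (0 to 1 in limma, 86 to 587 at an unadjusted p under 0.05), so 1 of 10 gave as many. For lists the real split gave 9 and the highest other 9, so 2 of 10 gave as many. Signal near background limits dim genes, Foxp3 in p300-deleted cells among them.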

Other observations

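The genes in this part were chosen after their values had been seen, and no test beyond the fit across genes was run on them.

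The checkpoint kinase Chek1 fell by 0.92 (SE 0.16, adjusted p = 0.0405), but it was at -0.45 with the mean of all its probe sets and passed under 7 of 14 alternatives. The replication factor Gins1 fell by 0.84 (adjusted p = 0.0343), thymidine kinase Tk1 fell by 0.77 (adjusted p = 0.0392), the exonuclease Exo1 fell by 0.75 (adjusted p = 0.0458; past the threshold under 7 of 14 alternatives), the uracil glycosylase Ung fell by 0.74 (adjusted p = 0.0223) and the histone chaperone subunit Chaf1b fell by 0.71 (adjusted p = 0.0223). The lactate transporter Slc16a1 fell by 0.78 (adjusted p = 0.0390), the adenylate cyclase Adcy6 fell by 0.90 (adjusted p = 0.01001) and Cmtm7 fell by 0.80 (adjusted p = 0.0241).

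Among the smaller rises were the inflammatory caspase Casp1 at 0.76 (adjusted p = 0.0223), the costimulatory ligand Cd86 at 0.74 (adjusted p = 0.0327), the IL-21 receptor Il21r at 0.65 (adjusted p = 0.0392) and Tnfsf13b, the B cell survival factor BAFF, at 0.54 (adjusted p = 0.0445; past the threshold under 5 of 14 alternatives). Il21 and its receptor gene thus both passed the threshold in the same direction. The endoplasmic reticulum protein Pdia4 was at 0.82 (adjusted p = 0.0913) and did not pass.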
